A study of Homo sapiens with 9 samples.

How the data were processed

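RNA-seq was analysed for 9 libraries of total RNA from SH-SY5Y, an established human neuroblastoma cell line. The labels put 3 libraries in the parental line (WT) and 3 in each of 2 clones, B7 and C12, in which HTT, the gene for huntingtin, was targeted. Per the labels' protocols, Cas9 protein and a synthetic guide RNA were electroporated as a complex, single cells were grown out by serial dilution, and clones were chosen by western blot and Sanger sequencing. RNA was treated with DNase before Illumina sequencing, per the labels' protocols.

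The authors deposited raw gene counts and a table of TPM values for the same libraries. Counts were made with HTSeq 0.11.0 and the genome build GRCh38 was used, per the submitters' processing notes. The aligner, the strand setting of the counting and the annotation release are not given in the sources used here. Because the strand setting is not given, reads from overlapping and antisense genes may be mixed in these counts, and genes with over 20% of their exon bases inside other genes are named with that share or left out. The deposited TPM values were an exact rescaling of the deposited counts: over 8949 genes with at least 200 counts, the largest deviation from a fixed gene-specific factor was 0.0295%. The counts were therefore used for every main result and TPM only as an alternative. The table holds 58302 genes, of which 58039 matched a gene ID in the GENCODE release 29 annotation (GRCh38) and 33792 had a count in at least 1 library. Coordinates and GC contents come from that annotation.

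Total counts ranged from 16168464 to 20348596 per library. The biological coefficient of variation within groups was 12.4%. In counts simulated for B7 vs WT from the real means and library sizes (16482 genes), the test recovered 58% of 50 genes changed 1.5-fold, 72% of 50 changed 2-fold and 95% of 100 changed 4-fold, with 14 false calls among 174. A simulated shift of 0.5 (log2) in the p53 target list was also recovered, with 0 of the other lists called at an adjusted p under 0.05. Genes were simulated independently, so this run could not show false list calls that arise from correlated genes. Far fewer genes were changed in the simulation than were called in the data, and libraries were drawn without shared deviations. Recovery and false calls may therefore differ in the data. Intervals given for counts cover counting error only.

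Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr on the 3 groups, quasi-likelihood F test, two-sided) in 1 fit of all 9 libraries with a mean per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 17228 genes tested. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM (counts scaled by TMM-adjusted library size). The contrasts were B7 vs WT, C12 vs WT and C12 vs B7, and the last is the test of whether the clones' effects differ. Genes were counted as shared when both clones were called against WT with the same sign. Both contrasts use the same WT libraries, so the overlap was set beside 20 simulated draws of unchanged clones against those libraries, and beside the overlap of independent lists. The 3 WT libraries cannot be divided into parts of at least 2 libraries each.

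Gene lists were tested with camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 36 lists with at least 5 tested members within each contrast. An estimated correlation and fry were run as alternatives. Camera asks whether members move relative to the other genes, and fry asks whether they move at all. A call by only 1 of these tests is therefore no conflict. The lists cover neuroblastoma cell states, markers of fibroblasts, smooth muscle, Schwann cell precursors and glia, matrix and adhesion, synapse and channels, signalling pathways, stress and protein turnover, metabolism, the cell cycle, p53 and interferon, huntingtin partners and the genes beside HTT, and gene families. The groups, the tests, the lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule names genes with an approved symbol (no clone-based names, long intergenic, micro or small nucleolar RNA genes, or pseudogenes) and a mean of at least 1 CPM: per contrast the 10 called genes with the largest rise and the 10 with the largest fall whose log-CPM values did not overlap between the groups, 12 shared genes in each direction by the smaller of both fold changes, and for each list up to 4 called members with the largest fold changes (list members also under 1 CPM). HTT is named throughout, and other list members may be named with their values. Some genes that meet this rule are not reported here. Genes with 1 to 3 counts over a group are given as a ratio of CPM with an exact conditional 95% interval. Against a group with 0 counts, a lower bound from 3 counts over the group is given.

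The alternative settings were RLE, upper quartile and total count scaling, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) with and without a filter and on log2(TPM + 0.1) with it, no count filter, a filter at 1 CPM in 3 libraries, fits of only the groups compared, other thresholds, a replicate block and leaving out each library in turn. After the libraries had been compared, 2 more were added: leaving out replicate 2 of both clones together, and a correction for GC content with a spline per library. Added later were list tests with upper quartile, total count and TPM scaling and a replicate block with only the clones in the fit. The labels do not say whether libraries with the same number shared a preparation. Deviations from the group mean correlated at 0.213, 0.662 and 0.440 between same-numbered B7 and C12 libraries, and at -0.223 to 0.0273 between same-numbered libraries of WT and the clones. B7 replicate 3 and C12 replicate 1 correlated at 0.445, and B7 replicate 1 and C12 replicate 3 at 0.229. These values single out replicate 2 and give no evidence of pairs among the other libraries. The fit with the numbers as pairs for C12 vs B7 alone is therefore only an alternative, with pairs that the labels do not give. The GC content was that of the longest transcript. The GC check covered 11554 genes with a mean of at least 5 CPM. Files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.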

Results

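Gene counts were compared between 9 total RNA libraries of SH-SY5Y cells, a human neuroblastoma line with features of immature sympathetic neurons. The parental line (WT) and 2 HTT-targeted single-cell clones, B7 and C12, had 3 libraries each. Total counts were 16168464, 17883280 and 20348596 in WT replicates 1 to 3. They were 17568851, 19113125 and 18113656 in B7, and 19278126, 17619443 and 16266319 in C12. Between 25225 and 26588 genes had a count in a library. Levels are mean CPM ± SD (n = 3 libraries per group), and changes are log2 fold changes ± the approximate SE. That SE can be too small for large changes of genes with few counts in a group. Adjusted p-values are from edgeR's quasi-likelihood test for genes and from camera for gene lists. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The comparisons ask which transcripts differ after targeting of HTT, and the pair of clones shows which differences recur in a second clone. No unedited or mock-edited clone was among the samples. Effects of editing and single-cell cloning therefore cannot be told apart from loss of HTT, even where both clones changed alike.

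HTT (ENSG00000197386) lies on the plus strand of chromosome 4 from 3041422 to 3243960 (GRCh38, GENCODE release 29). It was at 188, 211 and 168 CPM in the WT libraries, 106, 84.8 and 104 CPM in B7, and 86.4, 78.0 and 89.8 CPM in C12. HTT RNA stood at 51.9% of WT in B7 (-0.95 ± 0.11, adjusted p = 8.14e-05) and at 44.8% in C12 (-1.16 ± 0.11, adjusted p = 7.65e-05), lower in 6 of 6 knockout libraries. The difference between the clones did not pass the threshold (-0.21 ± 0.11, adjusted p = 0.237). A normal approximation gave a 95% interval from -0.42 to -0.0015. It ignores the few degrees of freedom of the quasi-likelihood test, so it is too narrow and cannot be read as excluding 0. The counts cover the whole gene and read neither the edited site nor the protein.

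**Figure D1:**
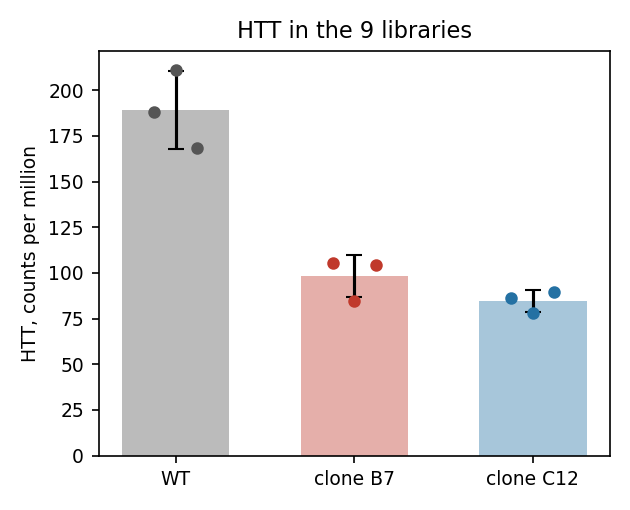
HTT level in CPM (vertical axis) in WT, clone B7 and clone C12, with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. The 6 knockout libraries lie between 78.0 and 106 CPM and the 3 WT libraries between 168 and 211 CPM.

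Along the first principal component of log-CPM (48.9% of the variance), WT libraries lay between -41.5 and -38.6, C12 between -7.33 and -6.64, and B7 at 46.7 or above. B7 replicate 2 and C12 replicate 2 stood apart within their groups. Genes in the highest quartile of GC content were lower in these libraries than in the others of the group, by a median log2 difference of -0.41 in B7 replicate 2 and -0.64 in C12 replicate 2. The 7SL and 7SK RNA genes held 0.456% and 0.269% of their counts, and 0.684% to 1.02% in the 7 other libraries. Across 11554 genes, which are not independent replicates, deviation from the group correlated with GC content at a Spearman coefficient of -0.717 and -0.820 in these libraries. In the WT libraries it was between -0.385 and 0.327, and in the other knockout libraries between 0.521 and 0.782. Each library was compared with the mean of the others of its group, so replicate 2 is in the reference of those knockout libraries. Their positive values may therefore mirror replicate 2.

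**Figure D2:**
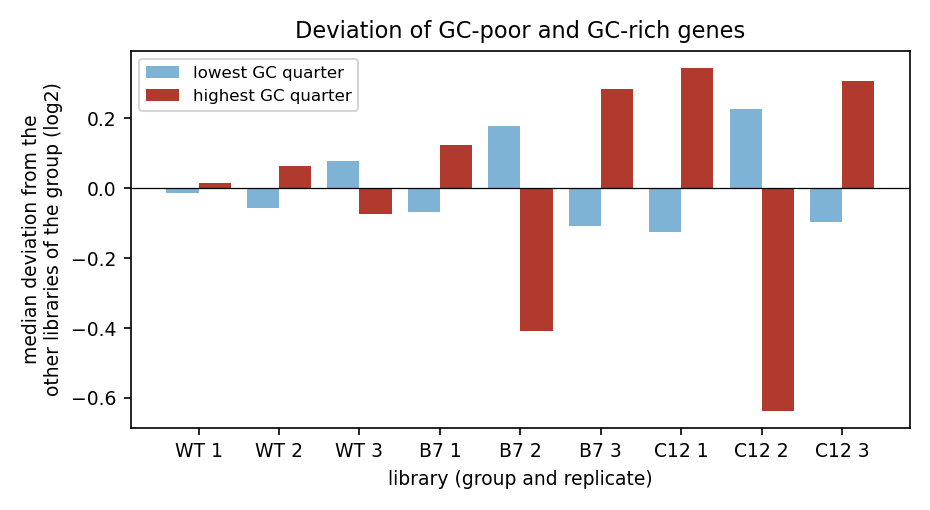
Median log2 deviation from the other libraries of the same group (vertical axis) for genes in the lowest and highest quartile of GC content, per library (horizontal axis). The highest quartile is at -0.41 in B7 replicate 2 and -0.64 in C12 replicate 2, while the lowest quartile is at 0.18 and 0.23.

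Among the largest changes of clone B7 against WT were those of a proneural factor, of 2 neurotrophin receptors and of a cytokine. NEUROG2, the proneural factor, fell from 53.1 ± 4.35 CPM in WT to 0.332 ± 0.161 CPM in B7 (-7.29 ± 0.19, adjusted p = 3.53e-09). NTRK2, the receptor for BDNF, fell from 129 ± 2.41 to 4.09 ± 0.464 CPM (-4.97 ± 0.09, adjusted p = 1.10e-09). NTRK3, the receptor for neurotrophin-3, rose from 0.142 ± 0.153 to 8.44 ± 0.810 CPM (5.92 ± 0.34, adjusted p = 4.61e-07). IL33, a cytokine, rose from 0.192 ± 0.204 to 21.9 ± 4.35 CPM (6.69 ± 0.39, adjusted p = 5.41e-07). In all, 4713 of 17228 genes (27.4%) were called, 2400 higher and 2313 lower, and 1513 of them differed at least 2-fold.

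Other large falls were those of NEBL (-5.78 ± 0.12), the glutamate receptor scaffold GRIP1 (-5.42 ± 0.30) and the netrin receptor UNC5D (-5.11 ± 0.18). The cadherin CDH20 (-5.03 ± 0.28) and DACH1 (-4.70 ± 0.20) fell too, and the artemin receptor GFRA3 went from 11.6 ± 0.616 to 0.353 ± 0.0710 CPM. Large rises included BMPER, a BMP-binding protein, from 0.479 ± 0.112 to 28.4 ± 0.350 CPM, and ODAM (5.43 ± 0.23). Some genes had only 1 to 3 counts over the WT libraries. For EDN1, the endothelin-1 gene, the ratio of CPM was 112 (95% counting interval 38.0 to 546). It was 66.7 for ANXA1 (22.5 to 326), 88.7 for HS3ST3A1 (30.0 to 433) and 67.5 for ANO4 (18.3 to 563).

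Neuroblastoma cells occur in a noradrenergic and a mesenchymal state. Of noradrenergic identity genes, 17 of 24 fell and 4 rose (17 and 4 adjusted over the list alone) in B7. Adjusted p was 9.25e-07 by camera, and adjusted p = 0.0960 with an estimated correlation. GCH1, which makes the cofactor of tyrosine hydroxylase, went from 172 ± 8.37 to 38.9 ± 4.28 CPM, and DBH, the enzyme that makes noradrenaline, from 1068 ± 34.9 to 277 ± 73.4 CPM. The noradrenaline transporter gene SLC6A2 fell as well (-1.75 ± 0.08). Of mesenchymal identity genes, 16 of 24 rose and 2 fell (17 and 2 adjusted over the list alone). Adjusted p was 1.18e-06 by camera, and adjusted p = 0.0127 with an estimated correlation. FOSL2 went from 7.29 ± 0.422 to 65.7 ± 2.02 CPM, and YAP1 (2.17 ± 0.11) and SPARC (1.99 ± 0.07) rose.

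Fibroblast and smooth muscle markers moved with the mesenchymal genes in B7: 6 of 8 rose and 1 fell (6 and 1 adjusted over the list alone). Adjusted p was 0.000267 by camera, and adjusted p = 0.0371 with an estimated correlation. They were led by the proteoglycan gene DCN, from 6.31 ± 0.616 to 175 ± 18.9 CPM (4.79 ± 0.13, adjusted p = 4.21e-09), and included COL3A1 (2.08 ± 0.12), while COL1A2 fell (-1.11 ± 0.22). Of matrix glycoprotein, proteoglycan and remodelling genes, 23 of 45 rose and 10 fell (24 and 11 adjusted over the list alone). Adjusted p was 0.00493 by camera, and adjusted p = 0.151 with an estimated correlation. FBN1 rose from 148 ± 9.87 to 522 ± 21.0 CPM, with GPC3 lower (-2.20 ± 0.12). Of integrins and cadherins, 14 of 27 rose and 6 fell (15 and 6 adjusted over the list alone). Adjusted p was 0.00730 by camera, and adjusted p = 0.0714 with an estimated correlation. ITGA5, a subunit of the fibronectin receptor, went from 1.54 ± 0.161 to 12.9 ± 1.66 CPM. The integrin and cadherin call ended with TPM (adjusted p = 0.0543). Schwann cell precursor and glial markers were called higher, where 4 of 9 rose and 1 fell (4 and 1 adjusted over the list alone). Adjusted p was 0.0466 by camera, and adjusted p = 0.150 with an estimated correlation. That call ended without B7 replicate 3 (adjusted p = 0.0632), C12 replicate 1 (0.0546) or C12 replicate 2 (0.0737), and without replicate 2 of both clones (0.158). It also ended with the GC correction (adjusted p = 0.0832) and upper quartile scaling (0.0602).

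Both neuronal lists called in B7 were lower. Of synaptic vesicle and exocytosis genes, 14 of 37 fell and 7 rose (15 and 7 adjusted over the list alone). Adjusted p was 0.00493 by camera, and adjusted p = 0.0886 with an estimated correlation. SV2C fell from 231 ± 20.8 to 68.3 ± 1.66 CPM, and the synapsin gene SYN1 (-1.13 ± 0.15) and the granin gene SCG3 (-1.18 ± 0.09) fell as well. Of neurotrophin and REST-linked neuronal genes, 18 of 30 fell and 4 rose (20 and 4 adjusted over the list alone). Adjusted p was 0.000231 by camera, and adjusted p = 0.0445 with an estimated correlation. Besides NTRK2 they included the neurofilament protein gene INA, from 147 ± 11.2 to 45.9 ± 4.10 CPM, the RNA-binding protein gene ELAVL3 (-1.18 ± 0.14) and BDNF (-1.23 ± 0.17). REST, a repressor of neuronal genes, rose from 108 ± 4.28 to 167 ± 7.34 CPM (0.63 ± 0.07, adjusted p = 5.06e-05).

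Cell cycle genes fell and p53 target genes rose in B7. Of proliferation genes, 32 of 35 fell and 0 rose (32 and 0 adjusted over the list alone). Adjusted p was 2.06e-12 by camera, and adjusted p = 0.0127 with an estimated correlation. PCNA fell from 336 ± 22.4 to 180.2 ± 9.85 CPM and MYCN from 7.85 ± 0.184 to 1.91 ± 0.419 CPM, with MCM4 (-0.91 ± 0.06) and E2F1 (-0.85 ± 0.18) lower too. Of p53 target genes, 19 of 29 rose and 1 fell (22 and 1 adjusted over the list alone). Adjusted p was 1.68e-09 by camera, and adjusted p = 0.0127 with an estimated correlation. The cell cycle inhibitor CDKN1A went from 48.8 ± 2.50 to 197 ± 12.6 CPM (2.01 ± 0.10, adjusted p = 2.23e-07). The death receptor FAS (2.89 ± 0.20) and SPATA18 (2.27 ± 0.12) rose, while PMAIP1 fell (-0.98 ± 0.14). Of replication-dependent histone genes, 40 of 64 fell and 0 rose (49 and 2 adjusted over the list alone). Adjusted p was 8.89e-12 by camera, and adjusted p = 0.403 with an estimated correlation. HIST1H2BM went from 147 ± 11.8 to 61.0 ± 9.68 CPM. The histone mean relative to WT was -0.87, -1.22 and -0.61 (log2) in B7 replicates 1 to 3, lowest in the library that was low in GC-rich transcripts.

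Interferon-stimulated and antigen presentation genes were higher in B7: 19 of 28 rose and 0 fell (20 and 0 adjusted over the list alone). Adjusted p was 1.89e-08 by camera, and adjusted p = 0.0127 with an estimated correlation. TAP1, the peptide transporter of antigen presentation, rose from 0.693 ± 0.214 to 4.04 ± 0.361 CPM, and IFI44 rose (2.98 ± 0.21). The RNA sensor gene IFIH1, with 1 to 3 counts over WT, had a ratio of CPM of 57.1 (95% counting interval 9.86 to 2295). Of Wnt pathway genes, 13 of 32 rose and 4 fell (15 and 5 adjusted over the list alone). Adjusted p was 0.00839 by camera, and adjusted p = 0.0811 with an estimated correlation. The secreted antagonist SFRP1 went from 53.4 ± 2.22 to 258 ± 11.8 CPM and the receptor FZD4 rose (2.50 ± 0.12). Without WT replicate 2 the Wnt call ended (adjusted p = 0.0566). Of TGF-beta and BMP pathway genes, 14 of 31 rose and 5 fell (18 and 5 adjusted over the list alone). Adjusted p was 0.00429 by camera, and adjusted p = 0.0960 with an estimated correlation. ID4 rose (2.79 ± 0.11), and the ligands BMP7 and INHBA fell (-3.43 ± 0.17 and -3.19 ± 0.10). Of clustered beta protocadherins, 9 of 15 rose and 0 fell (10 and 0 adjusted over the list alone). Adjusted p was 3.27e-05 by camera, and adjusted p = 0.0371 with an estimated correlation. PCDHB10 rose (1.17 ± 0.12), but these genes resemble each other in sequence, so reads may have been split between them.

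Of unfolded protein and integrated stress response genes, 13 of 26 fell and 1 rose (13 and 1 adjusted over the list alone) in B7. Adjusted p was 0.00398 by camera, and adjusted p = 0.0811 with an estimated correlation. PSAT1 went from 139.9 ± 9.06 to 59.6 ± 5.75 CPM, and HSPA5, an endoplasmic reticulum chaperone, fell (-0.30 ± 0.06). Of heat shock and chaperone genes, 13 of 27 fell and 3 rose (15 and 3 adjusted over the list alone). Adjusted p was 0.00493 by camera, and adjusted p = 0.403 with an estimated correlation. HSP90AA1 fell (-0.73 ± 0.11), while the small heat shock protein gene HSPB8 rose (2.60 ± 0.31). Of autophagy and lysosome genes, 12 of 37 rose and 1 fell (13 and 1 adjusted over the list alone). Adjusted p was 0.0475 by camera, and adjusted p = 0.165 with an estimated correlation. OPTN, an autophagy receptor (1.08 ± 0.10), and the lysosomal protease CTSB (0.79 ± 0.06) rose.

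Small shifts were called in 3 more lists of B7. Of HOX genes, 5 of 15 fell and 0 rose (5 and 0 adjusted over the list alone), such as HOXD8 (-0.54 ± 0.10). Adjusted p was 0.0466 by camera, and adjusted p = 0.151 with an estimated correlation. Of proteasome subunits, 5 of 34 fell and 1 rose (1 and 0 adjusted over the list alone). Adjusted p was 0.0120 by camera, and adjusted p = 0.601 with an estimated correlation. Of nuclear-encoded oxidative phosphorylation genes, 2 of 45 were higher and 2 lower (0 and 0 adjusted over the list alone), and the list was called lower. Adjusted p was 0.0263 by camera, and adjusted p = 0.625 with an estimated correlation. Leaving out single libraries ended the autophagy call (WT 1, WT 2, B7 2, B7 3, C12 1 or C12 2, adjusted p from 0.0531 to 0.0864) and the HOX call (WT 1, WT 2, B7 2, C12 1 or C12 2, 0.0537 to 0.0733). It also ended the proteasome call (WT 3 or B7 1, 0.0724 and 0.0668) and the oxidative phosphorylation call (WT 3, B7 1 or B7 3, 0.0632 to 0.108). The HOX call also ended with the GC correction (adjusted p = 0.202) and without replicate 2 of both clones (0.109). With camera on TPM the HOX, proteasome and oxidative phosphorylation calls ended (adjusted p of 0.0584 or more), and with fry the last 2 did (0.0743 and 0.0955).

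In B7 vs WT, 21 of the 36 gene lists were called by camera, 11 higher and 10 lower, and 7 with an estimated correlation. Leaving out replicate 2 of both clones raised the number of called genes to 7717 and a correction for GC content raised it to 7274, both alternatives chosen after seeing the data.

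**Figure D3:**
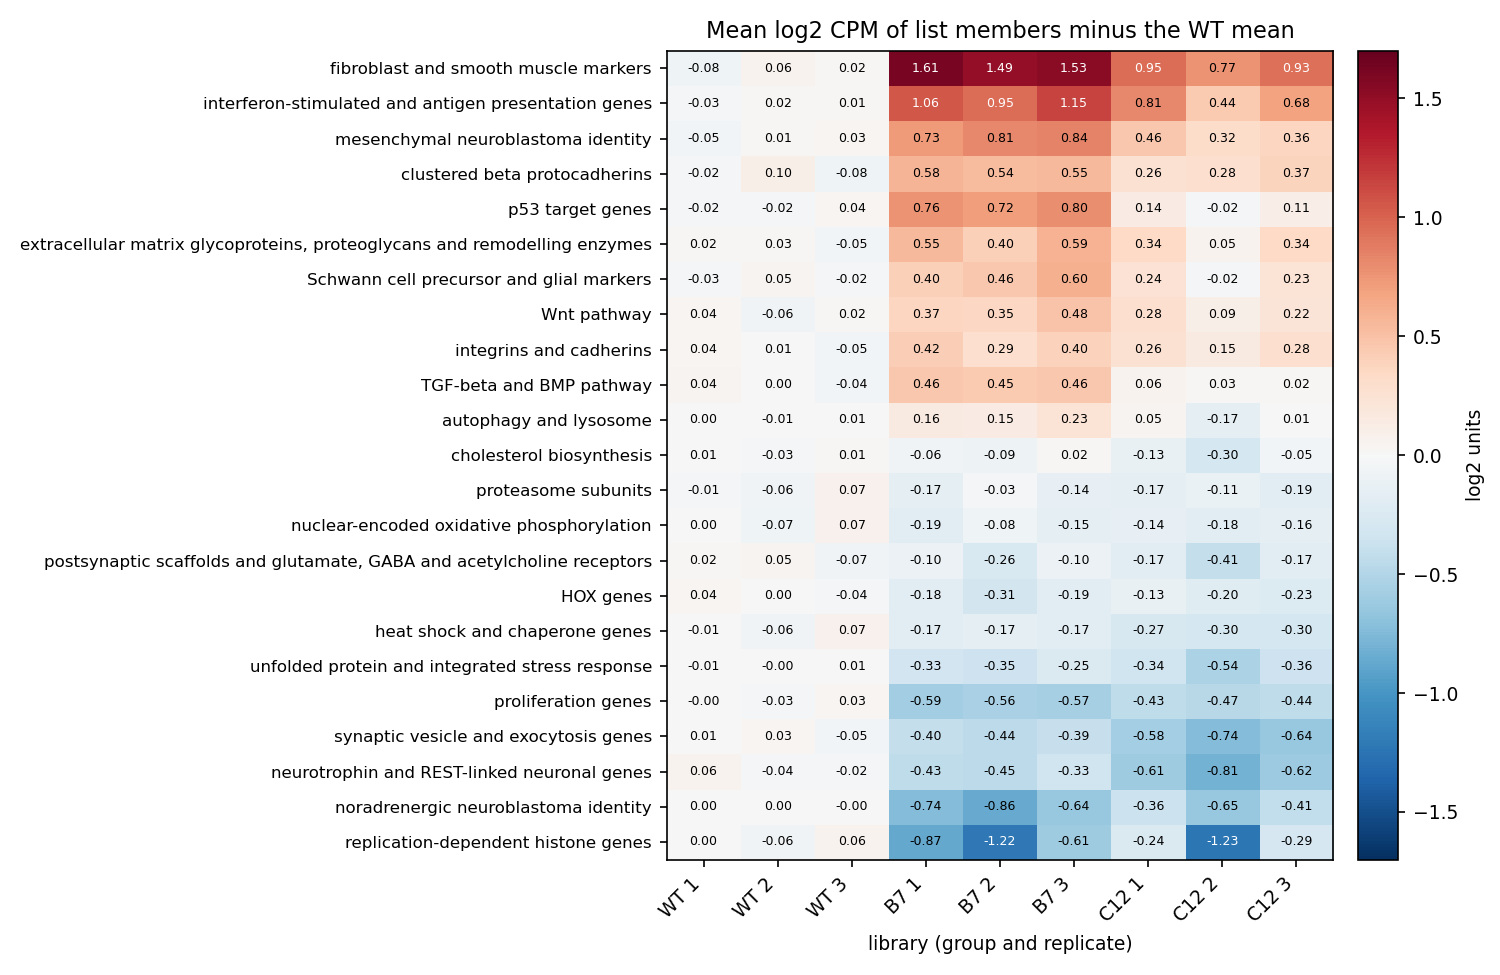
Mean log2 CPM of the members of each gene list called in a clone against WT, minus the mean of the WT libraries, in each of the 9 libraries (columns, group and replicate; lines, lists; colour scale in log2 units). Fibroblast markers range from 1.49 to 1.61 in B7 and from 0.77 to 0.95 in C12, p53 targets from 0.72 to 0.80 in B7 and from -0.02 to 0.14 in C12, and histone genes reach -1.22 and -1.23 in replicate 2 of the clones.

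Among the largest changes of clone C12 against WT were those of the matrix gene THBS2 and of SCG2, a gene of secretory granules. THBS2, a matrix thrombospondin, rose from 0.0738 ± 0.0241 to 3.65 ± 0.567 CPM (5.48 ± 0.32, adjusted p = 3.58e-06). FAM20C, a secretory pathway kinase, rose as well (3.70 ± 0.38, adjusted p = 0.000144). MARCH4, a ubiquitin ligase gene, fell (-3.08 ± 0.17, adjusted p = 2.46e-06). SCG2, which encodes the granin secretogranin II, fell from 249 ± 23.4 to 44.4 ± 4.61 CPM (-2.49 ± 0.11, adjusted p = 8.54e-07). In all, 2834 of 17228 genes (16.5%) were called, 1426 higher and 1408 lower, and 705 of them differed at least 2-fold.

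CFI rose further than FAM20C (4.82 ± 0.41), with 32% of its exon bases inside other genes. Other rises in C12 were those of IFI16 (3.55 ± 0.50), HEPH (3.18 ± 0.34), CD109 (3.12 ± 0.28) and NRP1, a semaphorin and VEGF co-receptor, from 4.46 ± 0.661 to 34.7 ± 1.37 CPM (2.96 ± 0.11). NUDT10 fell by more than SCG2, from 5.07 ± 0.453 to 0.172 ± 0.176 CPM (-4.76 ± 0.38), but it may share reads with the near-identical NUDT11. The potassium channel KCNH6 (-2.40 ± 0.21), the Notch ligand DNER (-2.33 ± 0.17) and the calcium-binding protein CALB1 (-2.13 ± 0.14) also fell. PTPRN, a dense-core vesicle protein, went from 53.6 ± 5.32 to 12.1 ± 5.88 CPM, and the dopamine receptor gene DRD2 from 16.6 ± 1.71 to 3.87 ± 1.40 CPM (-2.10 ± 0.24, adjusted p = 0.000293). NEUROG2 was not called in C12, at 44.8 ± 1.17 CPM (-0.24 ± 0.11, adjusted p = 0.174). NTRK2 fell to 61.8 ± 2.49 CPM (-1.06 ± 0.08), a smaller fall than in B7 (C12 vs B7, 3.91 ± 0.09, adjusted p = 1.18e-08).

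Of synaptic vesicle and exocytosis genes, 22 of 37 fell and 3 rose (23 and 4 adjusted over the list alone) in C12. Adjusted p was 1.28e-09 by camera, and adjusted p = 0.0129 with an estimated correlation. SYN1 went from 12.5 ± 1.34 to 3.48 ± 0.680 CPM, and SCG3 (-1.63 ± 0.10), SYT5 (-2.05 ± 0.27) and CPLX2 (-1.30 ± 0.14) fell. Of neurotrophin and REST-linked neuronal genes, 18 of 30 fell and 3 rose (20 and 3 adjusted over the list alone). Adjusted p was 1.28e-09 by camera, and adjusted p = 0.0129 with an estimated correlation. INA (-1.50 ± 0.09) and ELAVL3 (-1.58 ± 0.14) fell, whereas BDNF rose (0.69 ± 0.14, adjusted p = 0.00945). Of postsynaptic scaffold and receptor genes, 14 of 40 fell and 5 rose (15 and 5 adjusted over the list alone). Adjusted p was 0.0135 by camera, and adjusted p = 0.147 with an estimated correlation. The muscarinic receptor CHRM2 was among those that rose (2.08 ± 0.09). Without C12 replicate 2 the postsynaptic call ended (adjusted p = 0.0516). It also ended without replicate 2 of both clones (0.0694) and with the GC correction (0.0518). Of noradrenergic identity genes, 12 of 24 fell and 1 rose (16 and 1 adjusted over the list alone). Adjusted p was 1.88e-06 by camera, and adjusted p = 0.147 with an estimated correlation. DBH was at 334 ± 122 CPM (-1.68 ± 0.27) and DDC fell (-1.16 ± 0.08), but TFAP2B did not pass (0.05, adjusted p = 0.646). The noradrenergic mean relative to WT was -0.36, -0.65 and -0.41 in C12 replicates 1 to 3, lowest in replicate 2.

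Of mesenchymal identity genes, 8 of 24 rose and 1 fell (9 and 2 adjusted over the list alone) in C12. Adjusted p was 0.00860 by camera, and adjusted p = 0.0866 with an estimated correlation. RUNX1 (3.42 ± 0.52), YAP1 (1.01 ± 0.11) and FOSL2 (0.95 ± 0.10) rose. Of fibroblast and smooth muscle markers, 5 of 8 rose and 0 fell (5 and 0 adjusted over the list alone). Adjusted p was 0.000194 by camera, and adjusted p = 0.0340 with an estimated correlation. DCN was at 40.0 ± 4.73 CPM (2.66 ± 0.13, adjusted p = 1.46e-06), and FAP (1.32 ± 0.16) and COL3A1 (0.91 ± 0.12) rose, while COL1A2 did not pass (-0.18, adjusted p = 0.601). Of matrix genes, 14 of 45 rose and 8 fell (16 and 10 adjusted over the list alone). Adjusted p was 0.0121 by camera, and adjusted p = 0.201 with an estimated correlation. FBN1 was at 312 ± 15.0 CPM in C12 (1.08 ± 0.07). The matrix mean relative to WT was 0.34, 0.05 and 0.34 in replicates 1 to 3, and with TPM the matrix call ended (adjusted p = 0.182).

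Of interferon-stimulated and antigen presentation genes, 11 of 28 rose and 0 fell (15 and 0 adjusted over the list alone) in C12. Adjusted p was 1.79e-05 by camera, and adjusted p = 0.0323 with an estimated correlation. TAP1 was at 3.39 ± 0.294 CPM (2.28 ± 0.22), and NLRC5, an activator of MHC class I genes, went from 3.51 ± 0.687 to 12.6 ± 4.00 CPM. The interferon mean relative to WT was 0.81, 0.44 and 0.68. Of clustered beta protocadherins, 8 of 15 rose and 2 fell (11 and 2 adjusted over the list alone). Adjusted p was 0.00288 by camera, and adjusted p = 0.0909 with an estimated correlation. PCDHB10 was higher (0.96 ± 0.12) and PCDHB2 lower (-1.38 ± 0.23). Of Wnt pathway genes, 4 of 32 rose and 3 fell (5 and 3 adjusted over the list alone), including LGR5 (0.63 ± 0.07). Adjusted p was 0.0299 by camera, and adjusted p = 0.147 with an estimated correlation. Without C12 replicate 1 (adjusted p = 0.0567) and with TPM (0.0575) that call ended.

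Proliferation genes were lower in C12: 25 of 35 fell and 0 rose (33 and 0 adjusted over the list alone). Adjusted p was 8.70e-14 by camera, and adjusted p = 0.0129 with an estimated correlation. PCNA was at 209 ± 5.88 CPM (-0.69 ± 0.07), and E2F1 (-0.82 ± 0.18) and CCND1 (-0.53 ± 0.08) fell. Of replication-dependent histone genes, 19 of 64 fell and 1 rose (22 and 1 adjusted over the list alone). Adjusted p was 1.28e-09 by camera, and adjusted p = 0.448 with an estimated correlation. The histone mean relative to WT was -0.24, -1.23 and -0.29 in replicates 1 to 3, lowest in replicate 2. The histone call ended with fry (adjusted p = 0.0735). The mean log2 fold change of the list was -0.50, and -0.27 without replicate 2 of both clones (adjusted p = 8.07e-07). Of p53 target genes, 5 of 29 rose and 1 fell (7 and 1 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.344), though it was by fry (adjusted p = 0.00526). CDKN1A was at 52.2 ± 7.17 CPM in C12 (0.10, adjusted p = 0.568), and SPATA18 rose (0.76 ± 0.12).

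Of unfolded protein and integrated stress response genes, 14 of 26 fell and 0 rose (20 and 0 adjusted over the list alone) in C12. Adjusted p was 6.02e-08 by camera, and adjusted p = 0.0135 with an estimated correlation. HSPA5 went from 377 ± 8.91 to 236 ± 8.34 CPM, and MANF (-0.64 ± 0.11) and XBP1 (-0.60 ± 0.08) fell. Of heat shock and chaperone genes, 10 of 27 fell and 0 rose (16 and 0 adjusted over the list alone), including HSP90AA1 (-0.60 ± 0.11). Adjusted p was 1.81e-05 by camera, and adjusted p = 0.201 with an estimated correlation. Small shifts were called in 3 more lists. Of proteasome subunits, 9 of 34 fell and 1 rose (11 and 1 adjusted over the list alone), with PSMB2 as an example (-0.36 ± 0.06). Adjusted p was 0.000250 by camera, and adjusted p = 0.379 with an estimated correlation. Of oxidative phosphorylation genes, 4 of 45 fell and 0 rose (0 and 0 adjusted over the list alone). Adjusted p was 0.00258 by camera, and adjusted p = 0.448 with an estimated correlation. Of cholesterol biosynthesis genes, 3 of 25 fell and 0 rose (3 and 0 adjusted over the list alone), among them EBP (-0.55 ± 0.10). Adjusted p was 0.0232 by camera, and adjusted p = 0.147 with an estimated correlation. The cholesterol call ended without C12 replicate 2 (adjusted p = 0.0546) or replicate 2 of both clones (0.0694) and with TPM (0.0611). The oxidative phosphorylation call ended with fry (0.0502).

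In C12 vs WT, 17 of the 36 lists were called, 6 higher and 11 lower, and 6 with an estimated correlation. The number of called genes fell to 1487 without WT replicate 1 and 1512 without WT replicate 3, and rose to 6587 without replicate 2 of both clones and 5989 with the GC correction. The balance depended on scaling, with 2020 higher and 920 lower by upper quartile and 2497 and 3492 with the GC correction.

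Both clones were called with the same sign against WT in 1885 genes, 872 higher and 1013 lower, and with opposite signs in 94. Shared rises were those of NRP1 (3.98 ± 0.11 in B7 and 2.96 ± 0.11 in C12), the growth factor PDGFA (4.19 ± 0.27 and 2.92 ± 0.32) and the Notch target HES1 (2.07 ± 0.11 and 1.60 ± 0.11). Shared falls were those of DRD2 (-2.26 ± 0.25 and -2.10 ± 0.24), the homeobox gene DRGX (-3.82 ± 0.12 and -1.95 ± 0.11) and GPR19 (-1.83 ± 0.14 and -1.74 ± 0.13). KIF5C, a neuronal kinesin heavy chain, went from 312 ± 8.01 CPM to 172 ± 5.36 CPM in B7 and 146 ± 6.26 CPM in C12. The shared genes made up 36.3% of the higher and 43.8% of the lower calls of B7, and 61.2% and 71.9% of those of C12. Of them, 430 differed at least 2-fold in both clones, 658 also differed between the clones, and 69.5% had the larger fold change in B7.

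Independent lists of the same sizes would share 199 higher and 189 lower genes. The log2 fold changes of the clones correlated across 14932 genes, which are not independent replicates (r = 0.646), with a covariance of 0.188. Unchanged clones simulated against the same WT libraries gave a mean correlation of 0.504, a mean covariance of 0.0197 and at most 1 shared gene in 20 draws. No gene was changed in those draws, so a low number of shared genes was built in. It does not show how far noise in the WT libraries carries changed genes past the threshold in both contrasts. Libraries were drawn independently, so these draws lacked the deviation that replicate 2 of both clones shared. That deviation can add to the observed covariance and overlap, which the draws cannot rule out. The 3 WT libraries cannot be divided between the contrasts, so part of the excess may come from the shared controls. Shared changes may also follow from editing or single-cell cloning, which the parental line did not undergo. The balance depended on scaling: 1186 shared genes were higher and 678 lower with upper quartile, 1228 and 777 with total count and 986 and 341 with TPM scaling. With RLE scaling it was 890 and 1064, with DESeq2 698 and 995, and with the GC correction 1451 and 2518. The shared number fell to 1041 without WT replicate 1 and 1083 without WT replicate 3, and rose to 4399 without replicate 2 of both clones and 3969 with the GC correction.

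**Figure D4:**
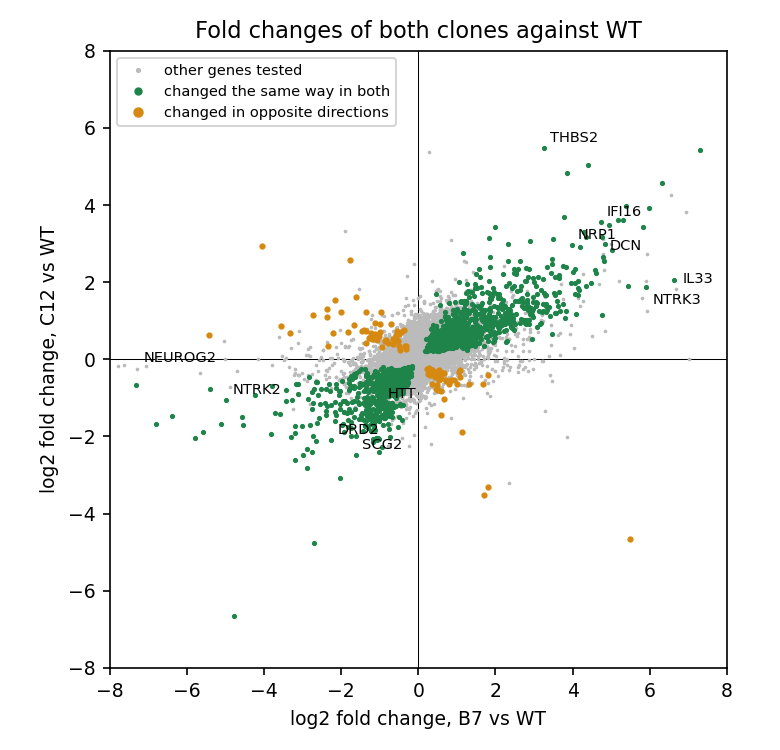
Fitted log2 fold change of every tested gene in B7 vs WT (horizontal axis) and C12 vs WT (vertical axis), with genes called in both clones coloured by whether the signs match (1885 genes) or differ (94 genes). NRP1 and DCN lie high in both clones and DRD2 and SCG2 low, while NEUROG2 is at -7.29 in B7 and -0.24 in C12; fitted values of genes with 3 or fewer counts in a group depend on the prior count.

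The clones also differed from each other. NEUROG2 was at 44.8 ± 1.17 CPM in C12 and 0.332 ± 0.161 CPM in B7 (C12 vs B7, 7.04 ± 0.19, adjusted p = 1.53e-08), and GRIP1 (6.04 ± 0.28) and GFRA3 (5.02 ± 0.18) were higher in C12 too. IL33 (-4.86 ± 0.32) and NTRK3 (-4.66 ± 0.29) were lower in C12, as was CCL2, a chemokine, at 15.1 ± 1.05 CPM in B7 and 1.13 ± 0.0587 CPM in C12. In all, 2814 of 17228 genes were called, 1139 higher and 1675 lower in C12, and 931 differed at least 2-fold. The homeobox gene LHX9 and the synaptic adhesion gene LRRTM4 fell in B7 (-3.31 ± 0.17 and -1.77 ± 0.21) and rose in C12 (0.69 ± 0.13 and 2.57 ± 0.16). SDK2 (-4.11 ± 0.30) and STOM (-4.04 ± 0.30) were lower in C12 than in B7, and GPR1 was higher (4.16 ± 0.18).

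The p53 target list separated the clones: in C12 vs B7, 17 of 29 were lower and 0 higher (24 and 0 adjusted over the list alone). Adjusted p was 3.14e-12 by camera, and adjusted p = 0.00835 with an estimated correlation. CDKN1A differed by -1.92 ± 0.10 (adjusted p = 6.65e-07) and FAS by -2.17 ± 0.18. Of mesenchymal identity genes, 14 of 24 were lower and 3 higher (14 and 3 adjusted over the list alone) in C12 relative to B7. Adjusted p was 2.42e-05 by camera, and adjusted p = 0.0311 with an estimated correlation. FOSL2 (-2.22 ± 0.10) and SPARC (-1.44 ± 0.07) were among those lower in C12. Of fibroblast markers, 4 of 8 were lower and 1 higher (4 and 1 adjusted over the list alone), with DCN at -2.12 ± 0.11. Adjusted p was 0.0214 by camera, and adjusted p = 0.141 with an estimated correlation. Without C12 replicate 2 the fibroblast call ended (adjusted p = 0.0580). Of matrix genes, 17 of 45 were lower and 7 higher (19 and 8 adjusted over the list alone). Adjusted p was 0.00377 by camera, and adjusted p = 0.209 with an estimated correlation. Of integrins and cadherins, 14 of 27 were lower and 5 higher (15 and 5 adjusted over the list alone). Adjusted p was 0.00986 by camera, and adjusted p = 0.102 with an estimated correlation. Of noradrenergic identity genes, 9 of 24 were higher and 4 lower (11 and 5 adjusted over the list alone), so that the list was higher in C12. Adjusted p was 0.00945 by camera, and adjusted p = 0.340 with an estimated correlation. TFAP2B was at 199 ± 2.39 CPM in B7 and 624 ± 22.1 CPM in C12. With a replicate block in a fit of the clones alone the noradrenergic call ended (adjusted p = 0.0815).

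Of synaptic vesicle genes, 16 of 37 were lower and 1 higher (18 and 3 adjusted over the list alone) in C12 relative to B7, including CPLX2 (-1.06 ± 0.14). Adjusted p was 0.00132 by camera, and adjusted p = 0.102 with an estimated correlation. Of neurotrophin and REST-linked genes, 13 of 30 were lower and 3 higher (15 and 3 adjusted over the list alone). Adjusted p was 0.00377 by camera, and adjusted p = 0.106 with an estimated correlation. Of immediate early genes, 8 of 23 were lower and 1 higher (9 and 1 adjusted over the list alone). Adjusted p was 0.000876 by camera, and adjusted p = 0.285 with an estimated correlation. EGR3 was at 4.93 ± 0.253 CPM in B7 and 0.935 ± 0.212 CPM in C12, and EGR1 was lower in C12 (-1.08 ± 0.09). Of voltage-gated ion channels, 16 of 41 were lower and 4 higher (18 and 6 adjusted over the list alone), with KCNA2 (-2.49 ± 0.20) and SCN4B (-1.77 ± 0.15) lower. Adjusted p was 0.000779 by camera, and adjusted p = 0.230 with an estimated correlation. Of TGF-beta and BMP genes, 14 of 31 were lower and 3 higher (18 and 4 adjusted over the list alone). Adjusted p was 0.000170 by camera, and adjusted p = 0.102 with an estimated correlation. BMP7 was higher in C12 (2.35 ± 0.17). Of interferon-stimulated genes, 10 of 28 were lower and 0 higher (15 and 0 adjusted over the list alone), with IFI44 lower (-1.38 ± 0.18). Adjusted p was 0.00158 by camera, and adjusted p = 0.102 with an estimated correlation. Of autophagy and lysosome genes, 9 of 37 were lower and 0 higher (9 and 0 adjusted over the list alone), with CTSB lower (-0.80 ± 0.06). Adjusted p was 0.00506 by camera, and adjusted p = 0.109 with an estimated correlation.

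Histone, zinc finger and proliferation genes were called higher in C12 than in B7. Of histone genes, 8 of 64 were higher and 1 lower (8 and 1 adjusted over the list alone). Adjusted p was 0.000341 by camera, and adjusted p = 0.675 with an estimated correlation. The histone call ended with fry (adjusted p = 0.346), and C12 replicate 2, at -1.23, was as low as the lowest B7 library, at -1.22. Of numbered zinc finger genes, 42 of 495 were higher and 9 lower (28 and 6 adjusted over the list alone). Adjusted p was 0.0209 by camera, and adjusted p = 0.675 with an estimated correlation. Of proliferation genes, 5 of 35 were higher and 1 lower (5 and 1 adjusted over the list alone). Adjusted p was 0.0374 by camera, and adjusted p = 0.285 with an estimated correlation. The proliferation call ended without WT 1, WT 2, B7 1, B7 3 or C12 2 (adjusted p from 0.0523 to 0.106), and the zinc finger call without B7 replicate 3 (0.178) or C12 replicate 2 (0.372). The zinc finger call also ended without replicate 2 of both clones (0.0517) and with fry (0.0872). Of huntingtin-associated protein genes, 5 of 31 were lower and 0 higher (5 and 0 adjusted over the list alone), including OPTN (-1.06 ± 0.10). Adjusted p was 0.0497 by camera, and adjusted p = 0.285 with an estimated correlation. That call ended without WT 1, B7 1, B7 2 or C12 3 (adjusted p from 0.0561 to 0.106) and with the GC correction (0.0565). It also ended with upper quartile (0.0680), total count (0.0881) and TPM scaling (0.0510) and with a replicate block (0.0542).

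**Figure D5:**
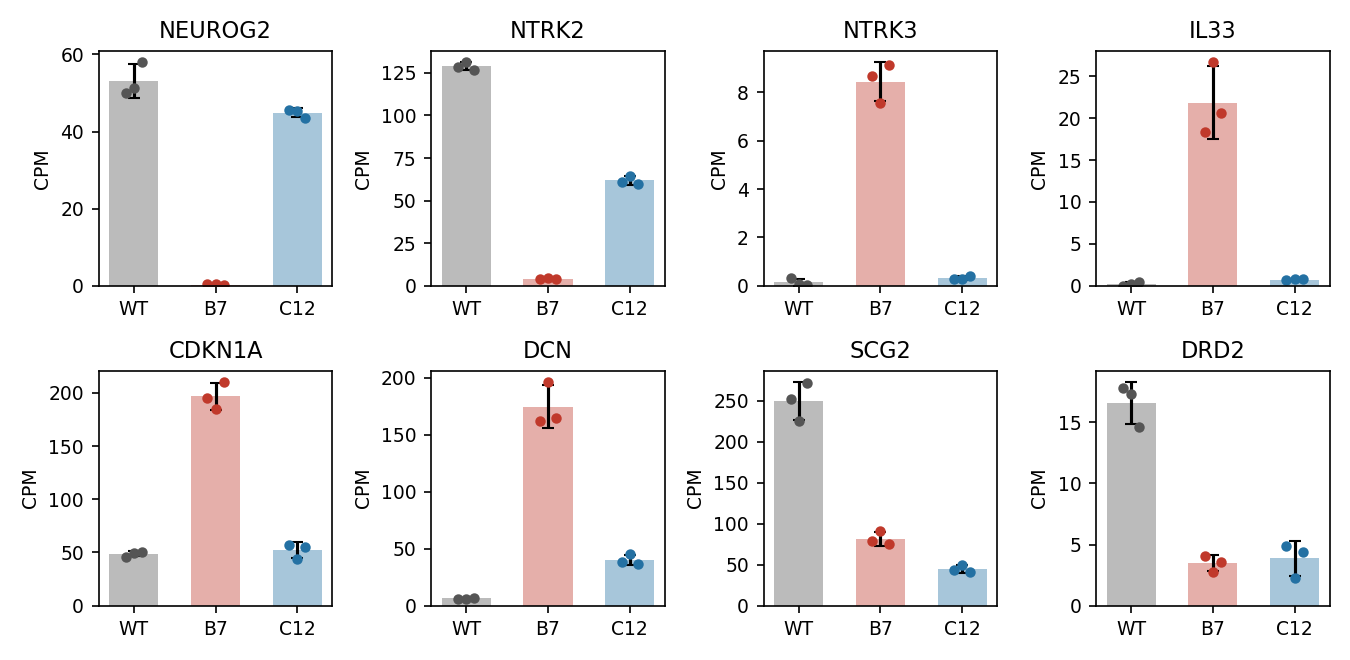
Level in CPM (vertical axes, starting at 0) of 8 genes in WT, B7 and C12, with bars for the mean of 3 libraries, error bars for the SD and points for libraries. NEUROG2 and NTRK2 are lowest in B7 (0.332 and 4.09 CPM), NTRK3, IL33, CDKN1A and DCN are highest in B7, and SCG2 and DRD2 are low in both clones.

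In C12 vs B7, 17 of the 36 lists were called, 4 higher and 13 lower, and 2 with an estimated correlation. Without replicate 2 of both clones 4301 genes were called, and with the GC correction 5099. With total count scaling 1745 genes were higher and 1429 lower in C12. With a replicate block in a fit of the clones alone, 5317 were called, and 2305 in the same fit without the block. The correlations between libraries gave no evidence of pairs beyond replicate 2.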

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

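The comparison of depth, the comparison with WT replicate 2, the comparison of HTT between clones, the comparison of collagen transcripts with DCN, the chromosome medians and both alternatives aimed at GC content were chosen only after the results were seen.

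The results singled out here are those in which the clones' effects differed in a direct test, C12 vs B7. This held for 2814 of the 17228 genes tested, for 186 of the 288 named genes and for 17 gene lists. Some genes were named because they were called in C12 vs B7, so the share among named genes is partly set by the naming rule. It is no measure of how common such differences are. The lists lower in C12 were p53 targets (adjusted p = 3.14e-12), mesenchymal identity (2.42e-05), TGF-beta and BMP (0.000170), voltage-gated channels (0.000779), immediate early genes (0.000876), synaptic vesicles (0.00132), interferon (0.00158), matrix (0.00377), neurotrophin and REST-linked genes (0.00377), autophagy (0.00506), integrins and cadherins (0.00986), fibroblast markers (0.0214) and huntingtin-associated proteins (0.0497). Those higher in C12 were histones (0.000341), noradrenergic identity (0.00945), numbered zinc finger genes (0.0209) and proliferation (0.0374). With an estimated correlation, 2 of these lists were called, p53 targets and mesenchymal identity.

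Of the named genes, 13 were called in opposite directions against WT. C12 exceeded B7 by log2 differences of 6.04 for GRIP1, 4.35 for LRRTM4, 4.00 for LHX9, 3.22 for ZNF385D, 2.88 for GPC3, 2.07 for NCAM2, 1.92 for BDNF, 1.15 for LAMA1 and 0.65 for HOXC10. It was lower than B7 by -1.54 for CHRNA7 and -1.08 for EGR1. Some of these calls are near the threshold: GRIP1 in C12 vs WT (adjusted p = 0.0256), and HOXC10 in B7 (0.0487) and C12 (0.0473), whose calls against WT ended without WT replicate 1, among others. The call of CHRNA7 in C12 vs WT (0.0128) also ended without WT replicate 1. Low counts allow only ratios for the remaining pair: POU4F2, a homeobox gene with 0 counts in C12, was at least 145-fold higher in B7 (floor of 3 counts over the group), and NDN, a member of the imprinted list with a mean under 1 CPM in every group and 1 count in C12, was 47.9-fold higher in B7 (95% counting interval 8.19 to 1931). Their falls in C12 against WT rest on few counts. POU4F2 had 9 counts over WT, at least 3.10-fold more than C12 (adjusted p = 0.0114). NDN had 13 counts over WT, a ratio of 13.4 over C12 (95% counting interval 2.02 to 572).

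B7 replicate 2 and C12 replicate 2 deviated from their groups together, with a correlation of 0.662 across genes. Lower depth is argued against, since B7 replicate 2 had 19113125 counts, the most of its group. A batch shared by all libraries numbered 2 is argued against too, since the higher of the correlations of WT replicate 2 with these libraries was -0.127. Removing the trend with GC content lowered the correlation to 0.335. That lies between the bounds set before this value was known, just above the lower one. A loss of GC-rich transcripts may therefore account for part of the correlation, and the remainder stays open. The labels give no biological difference between replicates, and no biological explanation was tested.

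The p53 target genes rose in B7, and the list differed between the clones. In C12 they were not called by camera, though they were by fry (adjusted p = 0.00526), which does not compare members with other genes. The loss of GC-rich transcripts is argued against as the whole cause, because with the GC correction the mean log2 fold change of the list in B7 was 0.73. Whether the rise follows from loss of huntingtin or is a property of clone B7 cannot be told apart with 1 line per clone: HTT was no lower in B7 than in C12 (log2 difference, C12 vs B7, -0.21), so a simple dose of HTT RNA may not account for it, but protein was not measured in these data.

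DCN and other fibroblast and mesenchymal markers rose in both clones. The 8 tested fibroblast markers all had counts in WT, and 5 of them also stand in other lists. Fibroblasts among the knockout cells would bring their abundant collagen transcripts: COL3A1 rose by 101% of the CPM rise of DCN in B7 and 137% in C12, which met a first test that asked for any of these collagens, but COL1A1 rose by only 10.7% and 16.5%, and COL1A2 changed by -1.94% and -2.14%. A stricter reading that rests on COL1A2 was made after these values were seen, so it cannot decide the question. COL3A1 moved as fibroblasts would bring it, and COL1A1 and COL1A2 did not. The loss of GC-rich transcripts is argued against, since the lowest log2 fold change of DCN over both clones and both alternatives was 2.56. No other explanation was tested.

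The covariance of the clones' fold changes, 0.188, exceeded the highest of 20 simulated draws of unchanged clones against the same WT libraries, 0.0205. Those draws lacked the deviation shared by replicate 2 of both clones, so the excess does not bear on that source. No chromosome had a median log2 fold change farther from 0 than -0.0896 in any contrast. Splits of the 6 libraries of each contrast number 10, too few for a share under 0.05. The splits took no account of the replicate numbers. In fits of the 2 groups alone, 1 of 10 splits, the real one, gave 5392 calls for B7 vs WT, 1 of 10 gave 2141 for C12 vs WT, and 1 of 10 gave 2305 for C12 vs B7. The highest of the other splits was 0 by edgeR, the only tool run on them, with at most 1423, 2022 and 2058 genes at an unadjusted p under 0.05. Each of these splits mixed libraries of both groups on each side, so differences between groups became spread within a side. Their 0 calls are therefore no measure of what chance alone would give. The splits that came nearest set WT replicate 2 with B7 1 and B7 3, WT replicate 2 with C12 1 and C12 3, and B7 1 and B7 2 with C12 2 against the rest.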

How the results depend on the processing

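Leaving out replicate 2 of both clones, the GC correction, the block with only the clones in the fit and the list tests with upper quartile, total count and TPM scaling were chosen only after the results were seen; all other alternatives had been set beforehand, and all were run. Of 613 gene results, 329 kept their direction and their side of the threshold under every alternative that tested them (filters and other tests left as few as 549 of them), and over 15948 comparisons 1643 lost the call and 0 reversed. Of 108 list results 55 were called, and 36 of these stayed called under every alternative run on lists (RLE, upper quartile, total count and TPM scaling, replicate block, fry, GC correction, libraries left out) other than an estimated correlation, which left 7, 6 and 2 lists for B7 vs WT, C12 vs WT and C12 vs B7.

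Stricter thresholds lowered the counts by construction. At an adjusted p under 0.01, 3036, 1279 and 1653 genes were called and 916 shared. At least 2-fold changes numbered 1513, 705 and 931, with 430 shared, and HTT in B7, at -0.95, missed that bound. Tested against 1.5-fold, 1389, 391 and 779 were called and 281 shared. With limma on log2(TPM + 1), C12 vs B7 had 1801 calls, with log2(TPM + 0.1) 1663. With TPM and no filter, C12 vs WT had 1540, C12 vs B7 1691 and the shared set 972; the cause was not tested. Without replicate 2 of both clones, 7717, 6587 and 4301 genes were called and 4399 shared. With the GC correction, 7274, 5989 and 5099 were called and 3969 shared. These alternatives kept between 94.3% and 99.1% of the main calls, and the spread within groups fell from 12.4% to 4.67% and 6.07%.

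Leaving out 1 library at a time gave 3421 (without B7 1) to 5914 (without C12 2) calls for B7 vs WT, 1487 (without WT 1) to 3696 (without C12 2) for C12 vs WT, 1931 to 3326 for C12 vs B7 and 1041 (without WT 1) to 2440 shared. HTT ranged from -1.02 to -0.86 in B7 and from -1.24 to -1.08 in C12. Lists called ranged from 18 to 22, 17 to 19 and 14 to 19.

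Some scalings moved the balance of calls toward higher and others toward lower. In C12 vs WT, 50.3% of calls were higher in the main result, 68.7% with upper quartile (2020 higher, 920 lower) and total count scaling (2254 and 1025), 79.5% with TPM (1784 and 461), 49.3% with RLE, 42.1% with DESeq2 (1071 and 1474) and 41.7% with the GC correction (2497 and 3492). In B7 vs WT the share was 50.9%, 66.4% with TPM (2382 and 1205), 58.6% with upper quartile, 52.0% with total count, 51.1% with RLE, 50.7% with DESeq2 and 42.9% with the GC correction. In C12 vs B7 it was 40.5%, 55.0% with total count scaling (1745 and 1429), 47.8% with TPM, 47.3% with the GC correction, 45.6% with upper quartile, 39.1% with RLE and 35.0% with DESeq2. TPM scaling shifted the median of all genes by 0.10 in B7 and 0.16 in C12, which also moves the mean log2 fold change of a list. The camera test compares members with the other genes. A shift common to all genes therefore does not account for list calls lost or gained with TPM. DESeq2 called 4221, 2545 and 2505 genes and limma-voom 4698, 2870 and 2775. The shared set was 46.3% higher in the main result, 63.6% with upper quartile (1186 higher, 678 lower), 61.2% with total count (1228 and 777), 74.3% with TPM scaling (986 and 341), 45.5% with RLE (890 and 1064), 41.2% with DESeq2 (698 and 995) and 36.6% with the GC correction (1451 and 2518). With the replicate numbers as a replicate block, 4784, 2857 and 2814 genes were called, 1902 shared, and 18, 17 and 16 lists: the Schwann cell precursor (adjusted p = 0.0619), autophagy (0.0522) and HOX lists (0.0529) of B7 and the huntingtin-associated list of C12 vs B7 (0.0542) missed the threshold. With only the clones in the fit, the replicate block gave 5317 calls and 16 lists for C12 vs B7, without the noradrenergic list (0.0815), and changed no call of a gene named for that contrast. Of the 53 lists not called in a contrast, 27 were called in at least 1 alternative. At 16168464 to 20348596 counts a library, genes near 1 CPM have few counts per library, and their folds depend most on counting error.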

Other observations

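The groups of genes in this part were taken from lists fixed beforehand, except the region of chromosome 19, which was chosen after its values were seen.

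Developmental signalling genes moved in both directions within their lists. Of Notch pathway genes, 7 of 24 rose and 4 fell (7 and 4 adjusted over the list alone) in B7 and 5 of 24 rose and 4 fell (5 and 4 adjusted over the list alone) in C12 (adjusted p = 0.966 and adjusted p = 0.663). The Notch mean relative to WT was -0.23 and -0.54 in replicate 2 of B7 and C12 and 0.08 to 0.22 in their other libraries, and without replicate 2 of both clones the mean log2 fold change in C12 turned from -0.04 to 0.13. NOTCH1 rose from 2.64 ± 0.238 CPM to 18.7 ± 7.90 CPM in B7 and 8.60 ± 3.66 CPM in C12 and HES1 from 6.21 ± 0.440 to 26.1 ± 0.201 and 18.8 ± 1.73 CPM, while HEY1, also a Notch target, fell from 66.8 ± 5.66 to 19.1 ± 1.71 and 27.3 ± 0.552 CPM and the inhibitory ligand gene DLK1 fell to 20.3 ± 4.23 CPM in B7 from 132 ± 4.93 CPM. Of axon guidance genes, 18 of 55 rose and 12 fell (20 and 12 adjusted over the list alone) in B7 (adjusted p = 0.185) and 11 of 55 rose and 6 fell (12 and 6 adjusted over the list alone) in C12 (adjusted p = 0.348). SEMA3A, a ligand of NRP1, rose in both (2.80 ± 0.13 and 2.04 ± 0.13), as did NRP1 itself, and the netrin receptor gene DCC fell in B7 (-2.30 ± 0.26). The axon guidance mean relative to WT was -0.05 and -0.21 in replicate 2 of B7 and C12 and 0.20 to 0.35 in their other libraries. Without replicate 2 of both clones the list was called in B7 (adjusted p = 0.00715) and C12 (adjusted p = 0.00886), and with the GC correction in B7 (adjusted p = 0.0257) but not C12 (adjusted p = 0.0577). Of retinoid pathway genes, 7 of 17 fell and 4 rose (7 and 4 adjusted over the list alone) in B7 (adjusted p = 0.385) and 4 of 17 fell and 2 rose (7 and 2 adjusted over the list alone) in C12 (adjusted p = 0.199), with the receptor gene RARB lower in B7 (-1.97 ± 0.14). The retinoid mean was -0.36 in C12 replicate 2, and -0.06 and 0.01 in the other C12 libraries.

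Of imprinted genes, 12 of 26 fell and 6 rose (12 and 6 adjusted over the list alone) in B7 (adjusted p = 0.0825) and 9 of 26 fell and 3 rose (10 and 3 adjusted over the list alone) in C12 (adjusted p = 0.0712). NNAT, a paternally expressed gene, fell in B7 (-2.56 ± 0.14) and C12 (-1.16 ± 0.14), and DLX5 rose in B7 (1.81 ± 0.34). The imprinted list was called in C12 with the GC correction (adjusted p = 0.0356) and without replicate 2 of both clones (adjusted p = 0.0474), but not in B7 (adjusted p = 0.0831 and adjusted p = 0.0589). In C12 it was also called without WT replicate 1 (0.0352) or C12 replicate 2 (0.0366). With TPM (adjusted p = 0.0123 and 0.0372) and fry (9.25e-06 and 0.000234) it was called in both clones. Of numbered zinc finger genes, 61 of 495 fell and 27 rose (57 and 20 adjusted over the list alone) in B7 (adjusted p = 0.574) and 25 of 495 rose and 10 fell (9 and 4 adjusted over the list alone) in C12 (adjusted p = 0.191). In C12 the list was called higher with total count (0.0444) and TPM scaling (0.0225). ZNF676, ZNF729 and ZNF99, of a region of chromosome 19 with many KRAB zinc finger genes, were picked for few or no counts in B7. Of the 18 other genes among the 8 tested genes to either side (21397119 to 23416075, GRCh38), 12 were lower and 0 higher in B7 by edgeR, against 2 lower and 1 higher in C12. Of the 10 others with a numbered zinc finger symbol, 7 were lower in B7. ZNF208 went from 2.79 ± 0.486 CPM in WT to 0.652 ± 0.192 CPM in B7 and 3.07 ± 0.665 CPM in C12, and ZNF43 from 105 ± 1.15 to 79.4 ± 3.60 and 103 ± 6.08 CPM, while ZNF91 stayed at 67.3 ± 2.35 CPM in B7 (WT, 68.7 ± 4.26). ZNF676 and ZNF729 had 0 counts in B7, at least 13.9-fold and 16.6-fold lower than in WT. These genes share near-identical stretches, so the counts may be split between them; the covariance and chromosome tests do not bear on this cluster.

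Other lists were not called against WT. Of collagens and basement membrane genes, 8 of 23 rose and 4 fell (9 and 4 adjusted over the list alone) in B7 (adjusted p = 0.140) and 7 of 23 rose and 1 fell (7 and 1 adjusted over the list alone) in C12. With the GC correction the collagen list was called in B7 (adjusted p = 0.0200) and C12 (adjusted p = 0.00490), as it was without replicate 2 of both clones (adjusted p = 0.00969 and adjusted p = 5.81e-05). Its mean relative to WT was -0.01 and -0.41 in replicate 2 of B7 and C12 and 0.41 to 0.55 in their other libraries. Of voltage-gated channels, 15 of 41 were higher and 16 lower (15 and 16 adjusted over the list alone) in B7, adjusted p = 0.733. In C12, 8 of 41 were higher and 10 lower (10 and 14 adjusted over the list alone), adjusted p = 0.332. They were called with fry in B7 (adjusted p = 0.00516) and with TPM in C12 (0.0197). Of immediate early genes, 9 of 23 were higher and 2 lower (9 and 2 adjusted over the list alone) in B7, adjusted p = 0.154. In C12, 1 of 23 were higher and 5 lower (1 and 6 adjusted over the list alone), adjusted p = 0.0663. They were called in B7 without WT 1 (0.0430) or B7 2 (0.0379), and in C12 with TPM (0.0372) and without WT 3, C12 1 or C12 3 (0.0322 to 0.0463). Their mean in C12 was -0.48 in replicate 2, and -0.04 and -0.05 in replicates 1 and 3. Of postsynaptic genes in B7, 6 of 40 were higher and 13 lower (6 and 13 adjusted over the list alone), adjusted p = 0.244. Of cholesterol genes in B7, 3 of 25 were higher and 4 lower (3 and 4 adjusted over the list alone), adjusted p = 0.652. Of huntingtin-associated protein genes, 3 of 31 were higher and 2 lower (3 and 2 adjusted over the list alone) in B7, adjusted p = 0.966. In C12, 1 of 31 were higher and 4 lower (1 and 4 adjusted over the list alone), adjusted p = 0.0707, but the list was called with fry (0.00150) and without C12 1 (0.0460).

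Of 30 genes around HTT at 4p16.3, 1 of 30 were higher and 6 lower (1 and 6 adjusted over the list alone) in B7, adjusted p = 0.244. In C12, 0 of 30 were higher and 4 lower (0 and 4 adjusted over the list alone), adjusted p = 0.115, with SLBP lower in both clones (-0.49 ± 0.08 and -0.44 ± 0.08). Their mean relative to WT was -0.27 and -0.42 in replicate 2 of B7 and C12 and -0.03 to 0.05 in the other libraries of the clones. Without replicate 2 of both clones, the mean log2 fold change turned from -0.07 to 0.01 in B7 and from -0.10 to 0.02 in C12. Of alpha and gamma protocadherins, 3 of 31 were higher and 2 lower (2 and 2 adjusted over the list alone) in B7, adjusted p = 0.536. In C12, 2 of 31 were higher and 3 lower (2 and 3 adjusted over the list alone), adjusted p = 0.864. Of ribosomal protein genes, 2 of 78 were higher and 3 lower (1 and 0 adjusted over the list alone) in B7, adjusted p = 0.991. In C12, 0 of 78 were higher and 1 lower (0 and 0 adjusted over the list alone), adjusted p = 0.141. Of the mitochondrial-encoded genes, 0 of 13 were higher and 0 lower (0 and 0 adjusted over the list alone) in B7, adjusted p = 0.818. In C12, 0 of 13 were higher and 0 lower (0 and 0 adjusted over the list alone), adjusted p = 0.376. Without WT 2, the ribosomal (0.00377) and mitochondrial-encoded lists (0.0403) were called in C12. The other lists not called in C12 were Schwann cell precursor markers, of which 3 of 9 were higher and 1 lower (4 and 1 adjusted over the list alone), adjusted p = 0.210, and integrins and cadherins, of which 10 of 27 were higher and 4 lower (11 and 4 adjusted over the list alone), adjusted p = 0.0622. Of TGF-beta and BMP genes in C12, 5 of 31 were higher and 6 lower (5 and 8 adjusted over the list alone), adjusted p = 0.847. Of autophagy genes in C12, 3 of 37 were higher and 0 lower (2 and 0 adjusted over the list alone), adjusted p = 0.663. Of HOX genes in C12, 1 of 15 were higher and 3 lower (1 and 4 adjusted over the list alone), adjusted p = 0.0760. With fry the Schwann cell precursor (0.00140), integrin and cadherin (5.94e-05) and HOX lists (0.0117) were called in C12. Leaving out single libraries also called the integrin and cadherin list (WT 1, B7 1 or C12 3, 0.0264 to 0.0438) and the HOX list (WT 3 or C12 1, 0.0447 and 0.0493).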
